A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

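Ribosome footprint libraries of Saccharomyces cerevisiae were compared, 3 from cells expressing b2-DHFR (clogger) and 3 from cells expressing cytosolic DHFR (control), described per the labels as biological replicates. The deposited files hold raw whole-number footprint counts, 1 count per nucleotide position of each gene and of 1000 nt on either side, over 20719455 positions per file. Per the submitters' processing notes, CASAVA 1.8, cutadapt 2.8 and Bowtie 1.2.3 were used with genome build R64, without a role or an order for each tool. How the authors assigned a footprint to a position, and how reads that match several places were placed, is not stated. At positions whose 40 nt on either side are identical between 2 genes, TEF1 and TEF2 (1145 positions) and EFT1 and EFT2 (2128 positions) held equal counts at 100% of positions in all 6 libraries, so there shared footprints were counted in full at each copy. The positions are named as A sites, yet the counts peak on the start codon in all 6 libraries. They also peak on the last sense codon in the 4 libraries without cycloheximide. P sites would peak at both, so positions can lie 1 codon upstream of the A site. The frames of the CDS held 24.9 to 28.3%, 47.5 to 49.2% and 23.7 to 26.1% of footprints.

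Of 5917 genes in the files, 5911 matched the R64 gene table and 5881 were used, and 36 were left out since their length, start codon or stop codon in the files did not match the gene table. Of the genes used, 5552 are in 1 reading frame over their whole span. The others, such as spliced and mitochondrially encoded genes, were counted over their span with any intron, since no exon table was at hand. Footprints were summed per CDS, taken as this span, without the first 15 and last 5 codons and without positions shared by 2 CDSs of the same strand. This gave 16317110 to 23791880 footprints per library, and whole CDSs held 17552594 to 27123936. Shares of counts have 95% Wilson intervals from scipy. For the upstream share of control 2 the interval is 0.263 to 0.267%, and for clogger 2 it is 0.232 to 0.236%. Such intervals cover counting error only, since the reads carry no molecular identifiers that were available here. Between replicates of a group the chi-square per degree of freedom was 90.9 to 254, far above counting error, and no library was a copy of another.

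Clogger and control were compared in edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F-test, 5439 genes tested) with cycloheximide as a covariate, and adjusted p values are Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. TMM factors were 0.829 to 1.10, and CPM are counts over library sizes multiplied by these factors. The cycloheximide term came from the same fit and the interaction from a fit with the product of both terms. Gene lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation and with fry. Ratios of upstream to CDS footprints and of early to late CDS footprints were tested in edgeR as a region by clogger term with library, region and region by cycloheximide as covariates, over genes with a mean of at least 20 counts in the smaller region. Codon occupancy was the density at a codon over the gene mean, averaged over 913 genes with a mean of at least 5 counts per codon, without the first 20 and last 10 codons, and was tested in limma. Shares and density ratios were compared by exact two-sided permutation tests, for which 3 against 3 libraries cannot go below 0.1, 2 against 4 below 0.0667 and 2 against 2 below 0.333. DESeq2 1.42.0 was the second count tool. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

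The groups, tests, most alternatives, 31 gene lists and the rule for naming genes were set before the data were examined. The lists cover the proteasome and its regulators, chaperones and proteases of the cytosol, mitochondria and endoplasmic reticulum, pleiotropic drug resistance, autophagy, general and oxidative stress, peroxisomes, respiratory subunits and their assembly, the citric acid cycle, mitochondrial carriers, import and ribosomes, coenzyme Q, heme, HAP regulators, cytosolic ribosomes and their assembly, translation factors, aminoacyl-tRNA synthetases, amino acid synthesis, iron, sterols, histones, glycolysis, gluconeogenesis with lactate use, galactose use and genes with upstream open reading frames. COX5B, left out for its layout, and ARG5,6 were the 2 list names without a tested gene. Named for the clogger were the 12 genes with the largest rise and the 12 with the largest fall among genes that passed, had a mean of at least 10 CPM, changed the same way in all 3 same-numbered pairs and shared less than 20% of CDS 28-mers with other places. Up to 4 members of each list with the smallest adjusted p were also named, with CYB2, RPN4, PRE2, HSP82, HSP104, SSA4, HAP4, COX4, ATP5, CIS1, PDR3, PDR5, TOM70, TIM17, SSC1, GCN4, GAL1, GAL10, JEN1 and the mitochondrially encoded genes. For the cycloheximide, interaction and ratio tests the rule took the 5 largest rises and 5 largest falls that passed with a mean of at least 10 CPM, for upstream ratios also GCN4, CPA1, YAP1 and HAP4, and for codons the 4 with the smallest p. A few other genes are named where a small count or a list member called for it.

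Alternatives were DESeq2, no TMM factors, a filter of 1 count, whole CDSs, genes without shared 28-mers, a threshold of 0.01, replicate number as a block, no covariate, the 4 libraries without cycloheximide, and each library left out in turn. Flanks of 50 and 200 nt, an early part of 100 codons, shifts of the codon position and other windows at the start were also run. Chosen after seeing the data were CYB2 counted past the part in the fusion, CYB2 left out of its list, upstream flanks without the 3 nt next to the start codon, early to late ratios only of genes in 1 reading frame, and codons shifted 1 downstream. Deviations from group means correlated across genes at r = 0.63, 0.24 and 0.19 for the same-numbered clogger and control libraries 1, 2 and 3, above the 0.1 taken as a sign of pairing. Replicate 1 shares cycloheximide in both groups, and clogger 3 with control 2, of different number, had r = 0.20. The fit was tested on simulated counts of 5431 genes with the design of the clogger comparison. It recovered 6 of 67 genes changed 1.5-fold, 52 of 67 changed 2-fold and 66 of 66 changed 4-fold. It also called 15 of 5231 unchanged genes. Among all genes called in that simulation, these 15 false calls were a larger share than the adjusted p threshold allows. Calls in the clogger comparison may thus hold more false ones than the threshold implies. In a simulation of the early to late comparison over 4813 genes the fit recovered 29 of 100 genes changed 2-fold and 97 of 100 changed 4-fold. In both simulations the changed genes were drawn from those with higher counts, so recovery at lower counts was not tested. The early to late simulation set a single dispersion for all genes and held no cycloheximide effect.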

Results

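Ribosome footprints, the mRNA fragments that translating ribosomes protect from digestion, were counted in budding yeast that had grown on 2% lactate and received 0.5% galactose for 4.5 h. Galactose switched on b2-DHFR, a fusion protein that lodges in the import channels of mitochondria (the clogger), in 3 libraries, and DHFR that stays in the cytosol (the control) in 3 libraries. Library 1 of each group came from cells given cycloheximide, an inhibitor of translation elongation, for 2 min before harvest, and libraries 2 and 3 of each group had none. Counts over the tested parts of coding sequences (CDSs) were 22261226, 23554958 and 23791880 in control libraries 1 to 3 and 22098206, 21135226 and 16317110 in clogger libraries 1 to 3. Changes are log2 fold changes, clogger over control, ± an SE, with n = 3 per group. In edgeR fits this SE was derived as the absolute change over the square root of the quasi-likelihood F. For codons it is the moderated SE of limma. Levels are counts per 1000000 footprints of the library size scaled by TMM (CPM), mean ± SD over the libraries of a group. Gene positions are those of the R64 build. RNA sequencing was not analysed here, so a change in footprints holds both mRNA level and translation.

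The first comparison asked whether the footprints show the clogger itself, since b2-DHFR carries the start of cytochrome b2, the lactate dehydrogenase encoded by CYB2 (YML054C, chromosome XIII, 165533 to 167308). From CYB2 codon 16 to the end of the part that usual b2-DHFR fusions hold, the clogger libraries held 588131, 464251 and 418109 footprints and the control libraries 9119, 9469 and 10130. Over the rest of CYB2, from 11 codons past that end to 5 codons before the stop codon, the counts were 7712, 14624 and 6305 in clogger libraries and 10999, 7923 and 12888 in controls. The log2 ratio of footprint density between these parts was 7.20 ± 0.68 (SD, n = 3) in clogger libraries and 1.31 ± 0.33 in controls, a difference of 5.88, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. The footprints of each clogger library step down at the end of that part, as the plot of footprints along CYB2 shows. Counted only over the rest of CYB2, an alternative chosen after seeing the data, CYB2 itself had a log2 change of -0.04 and an adjusted p = 0.940 (edgeR).

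**Figure D1:**
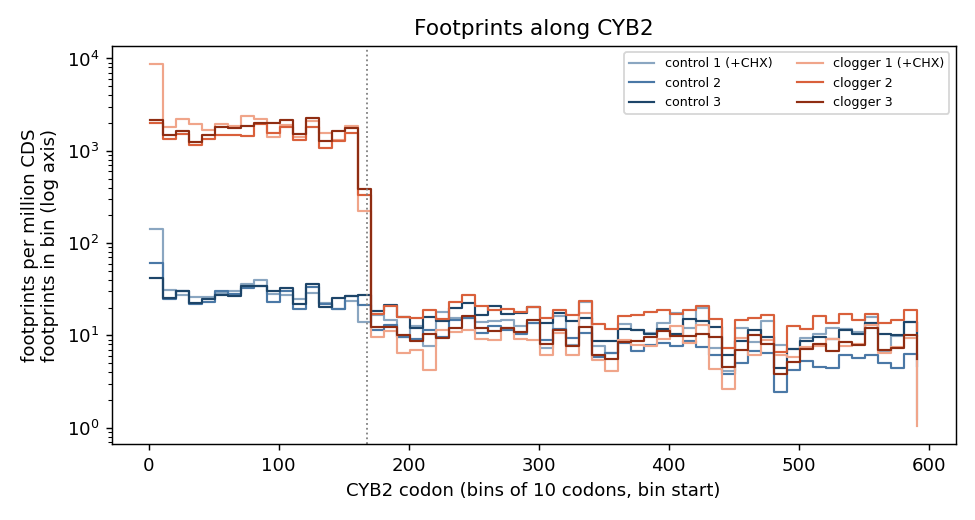
Footprints along CYB2 in bins of 10 codons (x axis, codon) per 1000000 CDS footprints of the library (y axis, log scale), 1 line per library, with a dotted line at the end of the part in the fusion. The clogger libraries lie above the control libraries up to that line. After it that gap is gone, with clogger 2 above all controls in many bins and clogger 1 below all of them in some.

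The main comparison asked which genes gained or lost footprints when import was clogged. Of 5439 genes tested, 392 rose and 328 fell (edgeR quasi-likelihood F-test, adjusted p under 0.05). Stress chaperones, proteasome subunits, drug pumps and minor forms of respiratory proteins were among the genes that rose, and subunits of the respiratory chain, enzymes of the citric acid cycle and ribosomal proteins were among those that fell. SDH9 (YJL045W, chromosome X, 356024 to 357928), a minor form of the flavoprotein of succinate dehydrogenase, had the largest rise among the genes chosen for naming, from 3.60 ± 0.571 to 183 ± 74.9 CPM, log2 5.68 ± 0.39. The Hsp70 chaperones SSA3 and SSA4, which heat induces, rose by 4.91 ± 0.39 and 3.23 ± 0.56. BTN2, which sorts misfolded proteins, rose by 3.09 ± 0.21, the small heat shock protein HSP26 by 2.62 ± 0.37, and the membrane heat shock protein HSP30 by 2.79 ± 0.45. ACS1, an acetyl-CoA synthetase, rose by 4.05 ± 0.33, to 266 ± 94.5 CPM. FAT3, which acts in fatty acid uptake, rose by 3.43 ± 0.56, the ABC transporter PDR15 by 3.27 ± 0.41, NCA3 by 3.08 ± 0.28, and ROQ1, which alters the substrates of a ubiquitin ligase under stress, by 2.65 ± 0.21. The rise of 4.73 ± 0.21 in CYB2 counts the footprints of the fusion.

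Among the genes that fell, OLI1 (Q0130, mitochondrial DNA, 46723 to 46953), which encodes the ring subunit of ATP synthase, changed by -3.02 ± 0.74. INO1, the first enzyme of inositol synthesis, fell from 3217 ± 1467 to 621 ± 269 CPM, log2 -2.33 ± 0.50. Methionine synthase MET6 changed by -2.24 ± 0.36, methylenetetrahydrofolate reductase MET13 by -2.10 ± 0.34, and the S-adenosylmethionine synthetase SAM2 by -2.05 ± 0.32. The aquaporin AQY2 changed by -2.21 ± 0.46 and the glycerol transporter STL1 by -2.09 ± 0.28. UPS2, which carries phospholipid between the mitochondrial membranes, changed by -2.02 ± 0.16. Glutamate dehydrogenase GDH1 changed by -1.84 ± 0.37 and mitochondrial citrate synthase CIT1 by -1.82 ± 0.29. YEL073C changed by -1.89 ± 0.46 and DMO1 by -1.69 ± 0.24. DMO1 had 373 and 133 CPM in control and clogger library 1, with cycloheximide, and at most 7.17 CPM in the other libraries.

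The number of genes that passed rested on which libraries were in the fit. It was 70 without control 1, 340 without control 2, 9 without control 3, 65 without clogger 1, 170 without clogger 2, 1163 without clogger 3, and 64 from the 4 libraries without cycloheximide. All 720 genes, picked as passing with all 6 libraries, kept their sign in each of these fits. Each fit reuses libraries from that selection, so this is no separate support. Without control 1 or clogger 1, the cycloheximide term fits the remaining cycloheximide library exactly. The clogger effect in those 2 fits and in that of the 4 libraries thus rests on the same 4 libraries. They are not separate checks. With 1 library left out at a time, 9 of the 720 passed each time: ACS1, BTN2, CYB2, SDH9, UPS2, HAC1 (1.94 ± 0.16), the lipase LPL1 (2.59 ± 0.14), the DNA repair glycosylase MAG1 (2.00 ± 0.13) and YOL131W (6.26 ± 0.41), the last 3 of which were named after their values were seen. Of 118 named genes that passed with all libraries, 36, 72 and 6 passed without control 1, 2 and 3, and 34, 56 and 114 without clogger 1, 2 and 3. DESeq2 called 1110 genes, 552 up and 558 down, among them all 720. Without TMM scaling factors 333 genes rose and 193 fell, and the median change of all tested genes was 0.14 in place of 0.03, a shift of 0.10. CAT8, FET3, HAP3, HTA2, MES1, MVD1, OLI1, PEX11, TIM22, TIS11, YEF3 and YEL073C did not pass then, and 4 other named genes newly passed. With replicate number as a block 806 genes passed, and among the named genes ERG6, HSP104, HXK1, JEN1, SSA2 and STI1 passed and MVD1, PEX11 and TIM22 did not, unlike in the fit with the cycloheximide term. Without any covariate 520 genes passed, and 23 named genes did not: AQY2, ATG16, CAT8, COQ8, DMO1, ERG13, ERG20, FET3, HSP78, HTA2, IDP2, ILV6, KAR2, MES1, MVD1, OLI1, PEX11, RPS24B, SIL1, TIS11, YEF3, YEL073C and YHR050W-A. Over whole CDSs CAT8, MVD1 and TIF1 did not pass, and GCN4 and HXK1 did.

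Gene lists fixed beforehand were tested with camera, and 23 of 31 were called, 12 up and 11 down. None of the 23 kept its call when the correlation between genes was estimated from the data, and fry, which asks whether a list moves one way on balance, called 7. Other splits of the 6 libraries into 3 against 3 called 9 to 22 lists, so a camera call alone separates the groups poorly here.

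Most proteasome subunits rose, and so did some of the other genes of protein quality control. All 33 proteasome subunits had a positive change: 23 rose and 10 did not pass, with a median of 0.72, and 31 rose when adjusted over the list alone. The proteasome list was called up (camera, adjusted p = 3.29e-13), with adjusted p = 0.460 with an estimated correlation. Its members SCL1, SEM1 and RPN12 rose by 0.87 ± 0.16, 0.86 ± 0.15 and 0.75 ± 0.14, and the catalytic subunit PRE2 by 0.89 ± 0.18. Of 22 proteasome regulators, assembly factors and ubiquitin shuttles, 8 rose (11 adjusted over the list alone), with a median of 0.51 and a call up at adjusted p = 1.85e-06, and adjusted p = 0.434 with an estimated correlation. They include RPN4, the transcription factor of proteasome genes, at 1.61 ± 0.13, polyubiquitin UBI4 at 1.67 ± 0.17, and UFD1 and NPL4, partners of the Cdc48 segregase, at 1.07 ± 0.12 and 0.90 ± 0.13. The proteasome's 23 rises became 9 without control 2 and 31 without clogger 3, and no subunit passed without any 1 of the other 4 libraries. The regulators' 8 rises became 2, 9 and none without control 1, 2 and 3, and 2, 5 and 12 without clogger 1, 2 and 3.

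Of 25 cytosolic chaperones, 12 rose and SNL1 changed by -0.93 ± 0.21 (17 and 1 adjusted over the list alone), with a median of 0.88. This list was called up at adjusted p = 9.24e-08, with adjusted p = 0.460 with an estimated correlation. Beside SSA3, SSA4, BTN2 and HSP26, the Hsp90 gene HSP82 rose by 1.57 ± 0.30 and the Hsp70 exchange factor FES1 by 1.36 ± 0.15, while the disaggregase HSP104 had 0.85 ± 0.24 and did not pass (adjusted p = 0.0655, or adjusted p = 0.0250 with replicate number as a block). Of 19 mitochondrial chaperones and proteases, 9 rose (16 adjusted over the list alone), with a median of 0.92. The list was called up at adjusted p = 9.24e-08, with adjusted p = 0.386 with an estimated correlation. The proteases YTA12, PCP1 and YME1 rose by 1.58 ± 0.19, 1.27 ± 0.14 and 1.21 ± 0.19 and the adaptor MGR3 by 1.22 ± 0.13, while the import motor SSC1 had 0.62 ± 0.29 and did not pass. Of 16 chaperones and degradation factors of the endoplasmic reticulum, 7 rose (13 adjusted over the list alone), with a median of 0.72, a call up at adjusted p = 4.38e-07, and adjusted p = 0.460 with an estimated correlation. The oxidoreductase ERO1 rose by 2.08 ± 0.21, HAC1, the transcription factor of the unfolded protein response, by 1.94 ± 0.16, the Hsp70 KAR2 by 1.55 ± 0.21 and its exchange factor SIL1 by 1.21 ± 0.14. The 12 rises of cytosolic chaperones became 2, 9 and 1 without control 1, 2 and 3, and 2, 6 and 16 without clogger 1, 2 and 3, while 1 member fell without clogger 2, 1 without clogger 3 and none without the others. In the same order the 9 rises of mitochondrial factors became 4, 5, none, 4, 3 and 10, and the 7 of the endoplasmic reticulum 2, 5, 1, 2, 4 and 8.

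Most genes of the drug resistance list rose, and some of autophagy, stress and peroxisomes. Of 13 genes of the pleiotropic drug resistance list, which includes CIS1 and MSP1, 9 rose (10 adjusted over the list alone), with a median of 0.82. The list was called up at adjusted p = 5.54e-06, with adjusted p = 0.386 with an estimated correlation. CIS1, which acts when import stalls, rose by 4.20 ± 0.47 to 5.20 ± 1.72 CPM, the pumps PDR15 and PDR5 by 3.27 ± 0.41 and 1.73 ± 0.19, and their activator PDR3 by 1.22 ± 0.18. Of 15 autophagy genes, 7 rose (9 adjusted over the list alone), with a median of 0.48, a call up at adjusted p = 1.99e-05, and adjusted p = 0.386 with an estimated correlation. The kinase ATG1 and the ubiquitin-like ATG8 rose by 1.41 ± 0.12 and 1.40 ± 0.18. Of 20 general stress genes, 3 rose (4 adjusted over the list alone), namely SPI1 by 2.18 ± 0.22, HSP12 by 2.08 ± 0.19 and NQM1 by 1.68 ± 0.29, with a median of 0.57, a call up at adjusted p = 0.0164, and adjusted p = 0.580 with an estimated correlation. Of 17 antioxidant genes, 5 rose and SOD2 changed by -0.78 (5 and 1 adjusted over the list alone), with no call for the list (median 0.33, adjusted p = 0.121). The peroxiredoxin AHP1 rose by 1.11 ± 0.23, and YAP1, a transcription factor of oxidative stress, by 1.08 ± 0.13. Of 18 peroxisome genes, 4 rose (6 adjusted over the list alone), with a median of 0.32, a call up at adjusted p = 0.00404, and adjusted p = 0.444 with an estimated correlation. Catalase CTA1 rose by 2.15 ± 0.35 and the thiolase POT1 by 1.22 ± 0.17. Without control 1, 2 and 3 and clogger 1, 2 and 3, the 9 rises of the drug resistance list became 2, 4, none, 1, 5 and 9, and the 7 autophagy rises 2, 4, none, 2, 2 and 8. In the same order the general stress rises became 2, 2, none, 2, 3 and 10, the antioxidant rises none, 2, none, none, 1 and 7 (with 1 fall without clogger 3 and none without the others), and the peroxisome rises 1, 1, none, 1, 2 and 5.

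Respiratory subunits fell while some of their minor forms rose. Of 41 nuclear-encoded subunits of the respiratory complexes and ATP synthase, with cytochrome c, 36 fell and 2 rose, also when adjusted over the list alone, with a median of -1.04. The list was called down (camera, adjusted p = 2.76e-21), with adjusted p = 0.386 with an estimated correlation. The ATP synthase subunits ATP20, ATP5 (YDR298C, chromosome IV, 1058176 to 1058814), ATP16 and TIM11 changed by -1.43 ± 0.16, -1.21 ± 0.14, -1.17 ± 0.14 and -1.11 ± 0.12, and the cytochrome oxidase subunit COX4 by -1.03 ± 0.17. The members that rose were CYC7, the minor cytochrome c, by 0.92 ± 0.14, and NDE2, a minor external NADH dehydrogenase, by 2.53 ± 0.34. Of 16 citric acid cycle enzymes, 9 fell (11, with 1 rise, adjusted over the list alone), with a median of -0.97, a call down at adjusted p = 5.86e-07, and adjusted p = 0.460 with an estimated correlation. IDH1 and IDH2, isocitrate dehydrogenase, changed by -1.66 ± 0.18 and -1.41 ± 0.17, fumarase FUM1 by -1.62 ± 0.18 and malate dehydrogenase MDH1 by -1.36 ± 0.19. Of 27 inner membrane carriers, 8 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.34, a call down at adjusted p = 1.83e-04, and adjusted p = 0.386 with an estimated correlation. The main ADP/ATP carrier PET9 fell from 3340 ± 522 to 1111 ± 129 CPM, log2 -1.58 ± 0.17, while its minor form AAC1 rose from 8.94 ± 4.15 to 34.7 ± 7.67 CPM, log2 2.03 ± 0.27. The phosphate carrier MIR1 and the citrate carrier YHM2 changed by -1.32 ± 0.18 and -1.28 ± 0.15. Without control 1, 2 and 3 and clogger 1, 2 and 3, the 36 falls of respiratory subunits became none, 25, none, none, 17 and 37, and the 2 rises 1, none, none, 1, 1 and 2. In the same order the citric acid cycle falls became 3, 8, none, 3, 5 and 9, and the carrier falls 1, 4, none, 1, 4 and 10. The rise of AAC1 did not pass without control 2 or control 3.

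**Figure D2:**
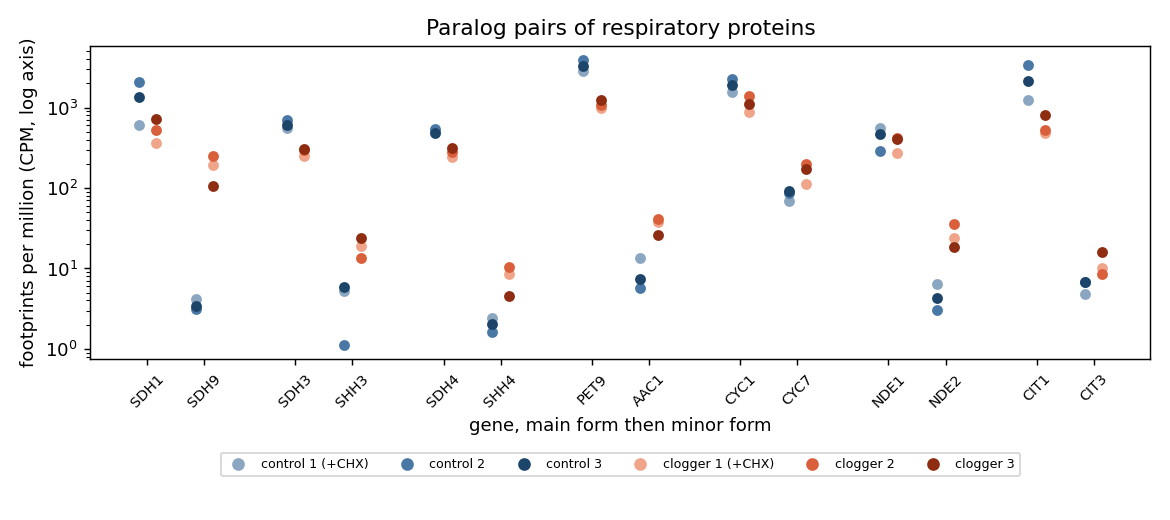
Footprints in CPM (y axis, log scale) of 7 pairs of paralogs (x axis, main form then minor form), 1 point per library. SDH9 lies at 3.60 CPM on average in control and 183 CPM in clogger libraries, and AAC1 at 8.94 and 34.7 CPM.

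Most genes of import, respiratory assembly and mitochondrial ribosomes did not pass. Of 40 genes of import and presequence processing, 4 rose, also when adjusted over the list alone, and the list was not called (median 0.05, adjusted p = 0.369). These were MIA40, which oxidises proteins of the intermembrane space, at 0.99 ± 0.19, and the translocase subunits TIM50, TIM54 and TIM22 at 0.82 ± 0.15, 0.67 ± 0.14 and 0.47 ± 0.11. The receptor TOM70 had -0.02 ± 0.16, or 0.08 without TMM factors, and TIM17 0.09 ± 0.11, and neither passed. Of 40 assembly factors of the respiratory complexes, 6 rose (7 adjusted over the list alone), among them MSS51 by 0.92 ± 0.14 and PET122 by 0.71 ± 0.15, with a median of 0.33, a call up at adjusted p = 2.99e-04, and adjusted p = 0.478 with an estimated correlation. Of 73 mitochondrial ribosomal proteins, 0 passed in edgeR, also over the list alone, 10 had an unadjusted p under 0.05 and 2 passed in DESeq2. That list was still called up (median 0.16, adjusted p = 0.00217), with adjusted p = 0.611 with an estimated correlation, and its member RML2 had 0.40 ± 0.12. Of 11 coenzyme Q genes, COQ6 and COQ8 rose by 1.17 ± 0.23 and 0.72 ± 0.14, also over the list alone, with a median of 0.35, a call up at adjusted p = 0.0185, and adjusted p = 0.580 with an estimated correlation. Of 8 heme synthesis genes, HEM14 rose by 1.05 ± 0.15 and HEM3 changed by -1.12 ± 0.12, also over the list alone, with no call (median -0.27, adjusted p = 0.168). Of the 5 HAP regulators of respiratory genes, HAP3 changed by -0.67 ± 0.14 and HAP4 by -0.14 ± 0.15, the latter without passing, and the list was not called (1 up and 1 down adjusted over the list alone, median 0.19, adjusted p = 0.957). Without control 1, 2 and 3 and clogger 1, 2 and 3, the import rises became none, 1, none, none, none and 5, and the assembly rises none, 1, none, none, 1 and 13. Without clogger 3, 7 coenzyme Q genes and 3 mitochondrial ribosomal proteins rose. COQ6, COQ8 and HAP3 passed in none of the fits without control 1, 2 or 3 or clogger 1 or 2, HEM14 passed in none of the same 5, and HEM3 did not pass without control 1, control 3 or clogger 1.

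Genes encoded by mitochondrial DNA have few footprints. OLI1 fell, from 27.0 ± 6.46 to 5.29 ± 6.75 CPM, with 1.36 and 1.42 CPM in clogger libraries 2 and 3 and 13.1 CPM in clogger library 1. The others did not pass: ATP8 had -1.92 ± 1.06, ATP6 -1.49 ± 0.66, COX3 -1.04 ± 0.62, COB -0.82 ± 0.41, COX2 -0.70 ± 0.69, COX1 -0.55 ± 0.51, SCEI 0.26 ± 0.44 and Q0255 0.71 ± 0.52, with VAR1 between COX3 and COB. OLI1 passed without control 1 or clogger 1, at -4.37 in both fits, whose clogger effect rests on the same 4 libraries without cycloheximide. It did not pass without control 2, control 3, clogger 2 or clogger 3, where its adjusted p was 0.132, 0.115, 0.133 and 0.103.

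Most cytosolic ribosomal proteins fell, and some translation factors and synthetases. Of 134 cytosolic ribosomal proteins, 120 fell (130 adjusted over the list alone), with a median of -0.73, and the list was called down (camera, adjusted p = 8.86e-49), with adjusted p = 0.386 with an estimated correlation. RPL9A, RPL1A, RPL1B and RPS24B changed by -1.14 ± 0.16, -0.84 ± 0.12, -0.78 ± 0.12 and -0.78 ± 0.12. Gene copies such as RPL1A and RPL1B share 88.7% of their 28-mers, and footprints of identical sequence were found counted in full at each copy where this was measured, so such copies are not independent. RPL9A, RPS24B, EFT1, EFT2, TIF1 and UBI4 also share more than 20%. Of 37 translation factors, 5 fell (7 adjusted over the list alone), with a median of -0.37, a call down at adjusted p = 2.01e-09, and adjusted p = 0.478 with an estimated correlation. Elongation factor 3, YEF3, fell, and the copies EFT1 and EFT2 of elongation factor 2 changed by -0.97 ± 0.19 each, and TIF1 of initiation factor 4A by -0.70 ± 0.15. Of 18 cytosolic aminoacyl-tRNA synthetases, 7 fell (18 adjusted over the list alone), with a median of -0.70, a call down at adjusted p = 8.51e-09, and adjusted p = 0.460 with an estimated correlation. DED81 changed by -0.99 ± 0.19 and TYS1 by -0.79 ± 0.15. Of 61 ribosome assembly factors, 0 passed in edgeR, also over the list alone, 8 had an unadjusted p under 0.05 and 4 fell in DESeq2. That list was called down (median -0.28, adjusted p = 2.17e-06), with adjusted p = 0.611 with an estimated correlation, and NOP58 in it had -0.70 ± 0.20. Without control 1, 2 and 3 and clogger 1, 2 and 3, the 120 falls of ribosomal proteins became 1, 93, none, none, 2 and 122. In the same order those of translation factors became none, 2, none, none, none and 11, and those of synthetases none, 2, none, none, none and 6. Without clogger 3, 51 ribosome assembly factors fell.

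Metabolic and other lists showed mixed changes. Of 43 genes of amino acid synthesis, 10 fell (17 adjusted over the list alone), such as ARO1 at -1.17 ± 0.21 and HOM2 at -0.99 ± 0.19, with a median of -0.61, a call down at adjusted p = 1.82e-06, and adjusted p = 0.560 with an estimated correlation. GCN4, their transcriptional activator, had -0.75 ± 0.20 and did not pass (adjusted p = 0.0557). Of 22 iron uptake genes, FET3, TIS11 and HMX1 fell, at -1.27 ± 0.31, -1.03 ± 0.21 and -0.88 ± 0.16, also over the list alone, with a median of -0.42, a call down at adjusted p = 0.00382, and adjusted p = 0.580 with an estimated correlation. Of 24 sterol synthesis genes, ERG20, ERG13 and MVD1 fell, at -0.80 ± 0.17, -0.65 ± 0.15 and -0.55 ± 0.13, also over the list alone, with a median of -0.22, a call down at adjusted p = 0.0168, and adjusted p = 0.386 with an estimated correlation. Of 8 core histone genes, HTA2 fell, at -0.61 ± 0.14 (4 adjusted over the list alone), with a median of -0.36, a call down at adjusted p = 0.00404, and adjusted p = 0.538 with an estimated correlation. Of 13 genes of gluconeogenesis and lactate use, ACS1 and CYB2, the latter through the fusion, rose, and IDP2 and CAT8 fell, at -0.89 ± 0.15 and -0.69 ± 0.17 (2 and 3 adjusted over the list alone), with no call (median 0.13, adjusted p = 0.770). The lactate transporter JEN1 had -1.34 ± 0.39 and did not pass, but passed with replicate number as a block (adjusted p = 0.0130). Without control 1, 2 and 3 and clogger 1, 2 and 3, the amino acid falls became none, 3, none, none, none and 12, and the iron falls none, 2, none, none, 3 and 3. The falls of sterol, histone and lactate genes passed in none of these fits but that without clogger 3, with 5, 4 and 3.

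Sugar use showed no call. Of 17 genes of glycolysis and fermentation, 0 passed in edgeR, in DESeq2, at an unadjusted p under 0.05 or over the list alone (median -0.14, camera adjusted p = 0.475). Of 8 galactose genes, 0 passed by the same 4 measures. The galactose list had a median of 0.05 and a mean of 0.04 where camera pointed down (adjusted p = 0.957). GAL1, galactokinase, had -0.21 ± 0.26, and GAL10 had -0.06 ± 0.23, or 0.04 without TMM factors. Of 20 genes with known upstream open reading frames, YAP1 rose, also over the list alone, and the list was not called (median -0.04, adjusted p = 0.565). YAP1 did not pass without control 1, control 3 or clogger 1, and without clogger 3 the list had 2 rises and 1 fall.

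**Figure D3:**
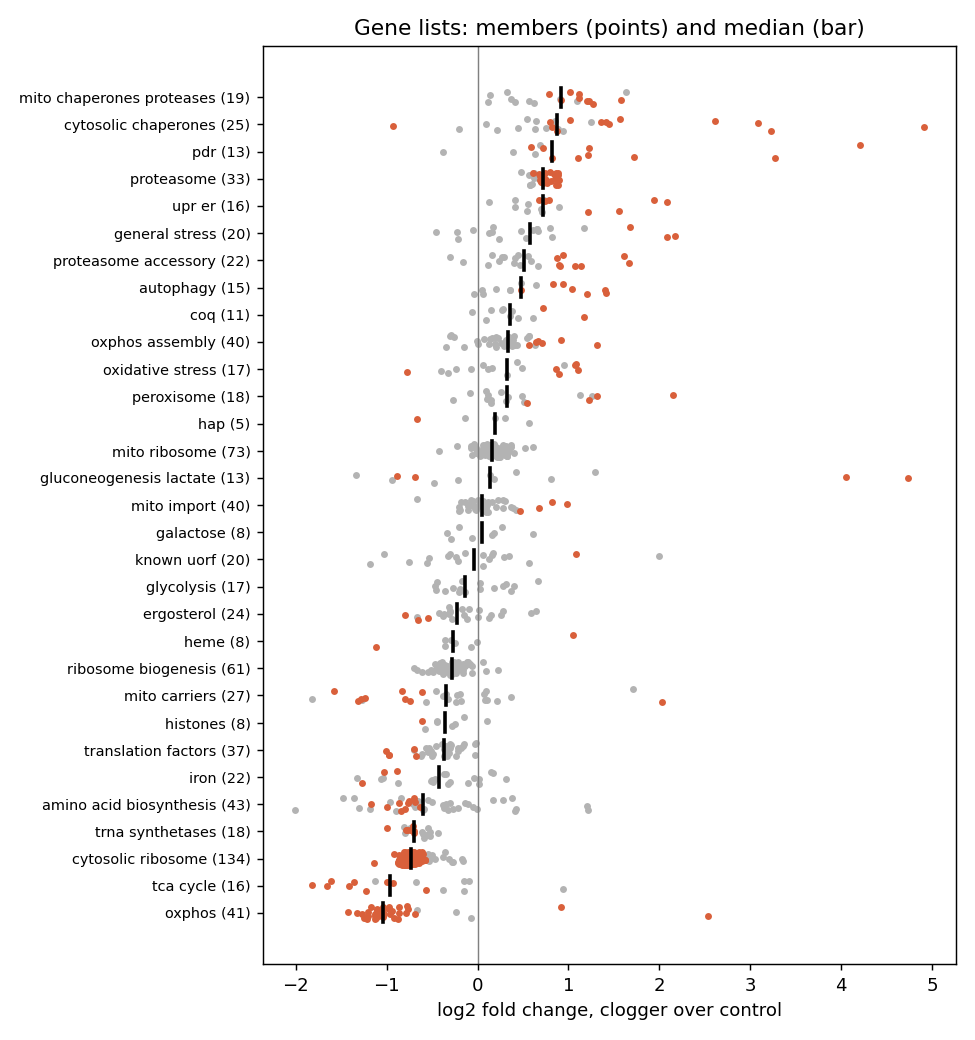
Log2 fold change, clogger over control (x axis), of the members of each list (points, coloured where they passed and grey where not) with the list's median (bar), 1 line of points per list with the number tested. Respiratory subunits have the lowest median, -1.04, and mitochondrial chaperones and proteases the highest, 0.92.

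The next comparison asked what cycloheximide before harvest changed, as library 1 of each group (2 libraries) against the other 4. This cannot be separated from any other difference of the replicate 1 cultures. Of 5439 genes, 24 passed, all higher with cycloheximide (edgeR). They include DMO1 at 6.23 ± 0.25, YHR050W-A at 5.15 ± 0.18, MIN9 at 3.18 ± 0.15, the transporter QDR1 at 2.62 ± 0.19, and RGL1, a regulator of Rho1 signalling, at 2.30 ± 0.17. The count was 3 without control 1, 12 without control 2, 3 without clogger 1, 265 in DESeq2, and 11 without TMM factors. With genes of 1 count or more it was 40, and over whole CDSs 41. DESeq2 had 202 of its genes higher and 63 lower with cycloheximide.

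Footprints near start codons differed far more with cycloheximide than with the clogger. The share over the 100 nt upstream of start codons was 3.62% in control 1 and 2.87% in clogger 1, against 0.265% and 0.271% in controls 2 and 3 and 0.234% and 0.251% in cloggers 2 and 3. With cycloheximide the mean was 3.24% ± 0.527 (SD, n = 2) and without it 0.255% ± 0.0164 (SD, n = 4), a 12.7-fold difference with an exact two-sided permutation p of 0.0667, the smallest that 2 against 4 libraries allow. Between clogger and control the difference was -0.265 percentage points (exact permutation p of 0.5) with all libraries and -0.0255 without the cycloheximide libraries. The share was lower in the clogger library of each of the 3 same-numbered pairs, with an exact paired permutation p of 0.25, the smallest that 3 pairs allow. Leaving out a library breaks a pair, and the unpaired difference was then 0.850 without control 1, -0.825 without control 2, -0.822 without control 3, -1.14 without clogger 1, 0.177 without clogger 2 and 0.168 without clogger 3. The share over the 100 nt after stop codons was lower in the clogger library of each of the 3 same-numbered pairs, at 0.109%, 0.0477% and 0.0512% against 0.174%, 0.0975% and 0.0938%, a mean difference of -0.0523 percentage points (exact permutation p of 0.3, or 0.25 when paired). That difference was -0.0262 without control 1.

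The density over codons 1 to 5, relative to codons 51 to 150 and averaged over 1352 genes, was 10.5 in control 1 and 11.3 in clogger 1, against 1.41, 1.25, 1.30 and 1.09 in control 2, control 3, clogger 2 and clogger 3. The clogger difference was 0.173, with an exact permutation p of 0.9, and turned to -0.131 without the cycloheximide libraries. It was 3.24, -1.32 and -1.40 without control 1, 2 and 3, and -3.20, 1.81 and 1.91 without clogger 1, 2 and 3. Leaving out any library unbalances cycloheximide between the groups, so the size of these swings follows from the difference of the cycloheximide libraries. The permutation p of 0.9 pools libraries with and without cycloheximide, so its spread holds that difference too. Start codons themselves had a density of 27.3 ± 1.62 (SD, n = 2) with cycloheximide and 2.69 ± 0.265 (SD, n = 4) without, and the last sense codon 1.12 ± 0.227 and 7.72 ± 1.44, as the plot around CDS ends shows.

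**Figure D4:**
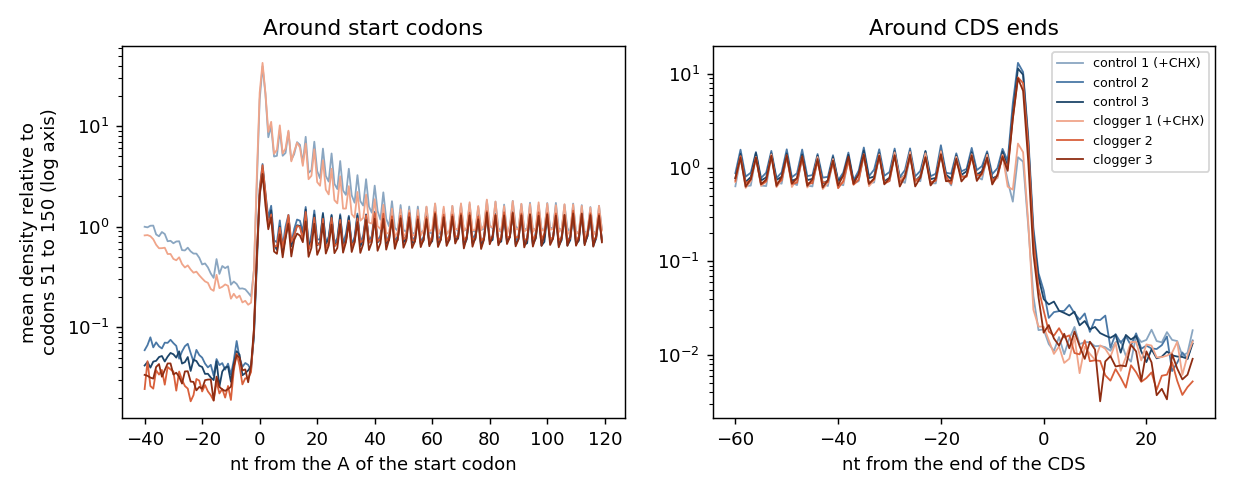
Mean footprint density relative to codons 51 to 150 (y axis, log scale) by nucleotide from the start codon (left) and from the end of the CDS (right), 1 line per library. The 2 cycloheximide libraries stand above the other 4 at start codons, 27.3 against 2.69, and below them at the last sense codon, 1.12 against 7.72.

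Whether the clogger effect itself differed with cycloheximide was asked by an interaction term. In edgeR 0 of 5439 genes passed, 25 had an unadjusted p under 0.05, and DESeq2 called 4. Without clogger 2, 19 passed, and without a cycloheximide library the term could not be fitted. OLI1 had an interaction of 3.52 ± 0.47, with an adjusted p = 0.779.

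The footprints upstream of start codons were then compared with those of the CDS of the same gene, to look for altered use of leader sequences. Of 2330 genes, OLI1 rose in this ratio and 8 fell (edgeR). Those that fell include the Hsp90 partners CPR6 at -2.15 ± 0.32 and STI1 at -1.50 ± 0.31, the Hsp70 proteins SSE2 at -1.80 ± 0.37 and SSA2 at -1.62 ± 0.24, and the mitochondrial disaggregase HSP78 at -1.46 ± 0.29. The ubiquitin-conjugating enzyme UBC4 changed by -1.35 ± 0.30, the ribosomal stalk protein RPP0 by -1.12 ± 0.24 and GAL1 by -0.95 ± 0.14. OLI1 had 3.19 ± 0.47. Its upstream counts were 103, 19 and 75 in control libraries 1 to 3 and 156, 34 and 47 in clogger libraries 1 to 3. Over its CDS the counts were 580, 448 and 802 in control and 306, 28 and 25 in clogger libraries. The rise of this ratio thus goes with the fall of OLI1 in CDS footprints and is no separate result. SSA2 shares more of its 28-mers with other places than the limit of 20% set for naming. GCN4, whose leader holds regulatory reading frames, had -1.29 ± 0.34 and did not pass (adjusted p = 0.0943), nor did CPA1 at -0.71 ± 0.36, YAP1 at -0.11 ± 0.39 or HAP4 at 0.03 ± 0.25. The median of all genes was -0.35, and without cycloheximide the upstream counts of CPR6, STI1, SSE2, SSA2 and HSP78 were 2 to 48 per library. The count of genes was 125, 6 and 4 without control 1, 2 and 3, 74, 4 and 12 without clogger 1, 2 and 3, 104 of 559 genes from the 4 libraries without cycloheximide, 4 with replicate number as a block (OLI1, GAL1, SSA2 and CPR6) and 0 without the cycloheximide term, where 1 gene had an unadjusted p under 0.05. With genes of 1 count or more it was 25, and also 25 without the 3 nt next to the start codon. Of the 104 genes from the libraries without cycloheximide, 18 rose and 86 fell.

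The early part of each CDS, codons 16 to 65, was compared with the rest of the same CDS, to see whether footprints shifted within genes. Of 4841 genes, 8 rose in this ratio and 2 fell (edgeR). Of the 4841, 159 are not in 1 reading frame over their span, as where an intron lies in it, and their early part need not be coding. RPS30A, which had risen, and TEF4 and APE2, both of the falls, are among them, so their ratios are not given. Over the 4682 genes in 1 reading frame, an alternative chosen after seeing the data, 6 rose and 0 fell. Cytochrome c CYC7 rose by 0.78 ± 0.13, the glycolytic TDH1, which shares 28.8% of its 28-mers with other places, by 0.74 ± 0.09, the ATPase SPF1 of the endoplasmic reticulum by 0.72 ± 0.13, glutamate synthase GLT1 by 0.62 ± 0.11, the vesicle coat protein SEC24 by 0.60 ± 0.10 and the chaperone HSP82 by 0.42 ± 0.07. The count over all 4841 genes was 176 without control 1, 159 without clogger 1, 4 without clogger 3, 171 from the libraries without cycloheximide, and 6 with an early part of 100 codons. It was 16 with genes of 1 count or more and 0 without the cycloheximide term, where 29 had an unadjusted p under 0.05. Of the 171 genes from the libraries without cycloheximide, 163 rose and 8 fell. The median change of this ratio over all genes was 0.07 in the main fit and 0.13 from the libraries without cycloheximide. The test is against 0, so the calls hold this general shift too.

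Occupancy of the 61 sense codons was compared over 913 genes. In limma 0 codons passed and 6 had an unadjusted p under 0.05. The smallest p belonged to CGC, ATG, CTA and GTG, with log2 changes of 0.08 ± 0.02, 0.07 ± 0.02, 0.05 ± 0.01 and 0.06 ± 0.02 and adjusted p of 0.353, 0.353, 0.353 and 0.408. The deposited positions peak on the start codon and, in the libraries without cycloheximide, on the last sense codon. The codon named here can thus lie 1 codon upstream of the one in the ribosome's A site. Counted 1 codon downstream, chosen after seeing the data, CGC, CTA and GTG turned to -0.10 ± 0.04, -0.06 ± 0.03 and -0.07 ± 0.04. ATG then had 0.04 ± 0.04, and 0 codons passed. The sign for CGC, CTA and GTG thus rests on which site the positions stand for.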

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

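All tests of explanations in this part were chosen only after the results were seen, except the slope across genes for upstream footprints.

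LTO1, an assembly factor of an iron-sulfur protein pathway and 1 of the 36 genes outside the comparisons, had 28.5 ± 0.764 footprints per 1000000 CDS footprints of the library, without TMM scaling (SD, n = 3), in clogger libraries and 20.4 ± 2.18 in controls, with each clogger library above each control. It stood out as a signal in data the comparisons did not use. Of 17 such genes with at least 1 on that scale, 1 lay above and 2, RPL20A and RPL20B, lay below the controls in all clogger libraries, and chance gives groups of 3 against 3 without overlap in 10% of cases.

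Minor forms of respiratory proteins rose where main forms fell. In 7 pairs picked for this pattern (SDH1 and SDH9, SDH3 and SHH3, SDH4 and SHH4, PET9 and AAC1, CYC1 and CYC7, NDE1 and NDE2, CIT1 and CIT3) the minor form rose in 6, with CIT3 at an adjusted p = 0.0659, and the main form fell in 6, with NDE1 at -0.24 ± 0.30. With 1 library left out at a time, SDH9 passed in 6 of 6 fits, AAC1 and NDE2 in 4 each, and SHH3, SHH4 and CYC7 in 1 each. Of the main forms PET9 passed in 5, SDH3 and CIT1 in 3 each, and SDH1, SDH4 and CYC1 in 1 each. Reads shared between copies are argued against by the share of 28-mers found elsewhere, at most 2.54% among the minor forms. Counting error alone is argued against by the lowest lower 95% limit of the count ratio, 1.78. That limit leaves out the spread between libraries, and pairs picked for a rise were likely to have a limit above 1. A candidate explanation is a change of isoform use under clogging, but how mRNA level and translation contribute was not tested, and the pairs were picked for what they show.

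The mitochondrially encoded OLI1 fell in the pairs without cycloheximide, from 1250 to 53 footprints summed over the pairs. Counting error alone is argued against by the upper 95% limit of the count ratio, 0.0706, which leaves out the spread between libraries. A loss of mitochondrial footprints as a whole stays open. OLI1 lay at least 2.40 SDs of the other 7 mitochondrial protein genes below their median. It had -3.99 against -0.35 in pair 2 and -4.52 against -1.94 in pair 3, but was picked as the lowest of them. The lowest other in pair 2, ATP8 at -3.94, had 1.33 CPM in control 2 and 0 in clogger 2. That value rests on the floor of the counts and also widens the SD in pair 2. In pair 3 all 7 fell, from -1.27 to -3.15. In the cycloheximide pair OLI1 had -0.85, and whether the pairs differ was not shown (interaction adjusted p = 0.779). A cause specific to OLI1 may add to this, and mRNA level, translation and recovery of its footprints were not tested. Over the 100 nt upstream of OLI1, controls 2 and 3 held 19 and 75 footprints, and cloggers 2 and 3 held 34 and 47.

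Of 8 genes whose ratio of upstream to CDS footprints fell, 5 encode chaperones or their partners, a theme seen only after the calls, and of these SSA2 and CPR6 alone passed with replicate number as a block. Upstream footprints that ignore the gene's own translation would give a slope near -1 across genes of the ratio's change on the CDS change. The slope over 2330 genes was -0.225 (95% limits -0.254 and -0.195), which argues against that as the whole cause across these genes. The limits treat genes of the same 6 libraries as separate. An average over all genes cannot settle the cause at the 5 chaperone genes. A general fall of the upstream share stays open: the 27 members of both chaperone lists with a ratio had a median of -0.64 against -0.35 over all genes, but less the part that goes with the CDS change it was -0.11, at percentile 10.8 of 10000 random sets of genes. Other transcript starts could add to this, which also stays open since no annotation of leaders was at hand.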

How the results depend on the processing

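Alternatives chosen only after the data were seen were CYB2 counted past the fusion, CYB2 left out of its list, upstream flanks without the 3 nt next to the start codon, early to late ratios only of genes in 1 reading frame, and codons shifted 1 downstream. The cause of the moves below was not tested, apart from what the design fixes. Fits without a library and the fit of the 4 libraries without cycloheximide have fewer samples. The stricter threshold has a smaller allowance. Fewer samples alone do not account for counts that rose in such fits. Without control 1 or clogger 1, the cycloheximide term of a clogger test fits the remaining cycloheximide library exactly. Such a fit rests on the 4 libraries without cycloheximide.

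Of 720 genes in the clogger comparison, DESeq2 gave 1110, a threshold of 0.01 gave 81, the 4 libraries without cycloheximide gave 64, and leaving out 1 library gave 9 to 1163. The other settings gave 520 to 806, the latter with replicate number as a block. For the 24 cycloheximide genes DESeq2 gave 265, no TMM factors 11, genes with 1 count or more 40, whole CDSs 41, and leaving out 1 library 3 to 24. For the interaction DESeq2 gave 4 and leaving out 1 library 0 to 19, and without a cycloheximide library it could not be fitted. For the 9 upstream ratios genes with 1 count or more gave 25, the flank without 3 nt 25, the replicate block 4, no covariate 0, the libraries without cycloheximide 104, and leaving out 1 library 4 to 125. For the 10 early to late ratios an early part of 100 codons gave 6, genes in 1 reading frame 6, genes with 1 count or more 16, no covariate 0, the libraries without cycloheximide 171, and leaving out 1 library 4 to 176. Where else the replicate block was run, on clogger genes, early to late ratios, codons and lists, it moved no count by over 1.5 times, and it was not run for cycloheximide or the interaction. Of 23 lists, an estimated correlation kept 0 and fry 7, and leaving out 1 library 18 to 23. Codons stayed at 0 in each setting run.

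The start window difference, 0.173, was -0.131 without the cycloheximide libraries and -0.152 over codons 1 to 15, and -3.20 to 3.24 with 1 library left out. The upstream share difference, -0.265, ranged from -1.14 to 0.850 with 1 library left out. In both, leaving out a library unbalances cycloheximide between the groups, from which the size of these ranges follows. The CYB2 ratio difference, 5.88, stayed between 5.64 and 6.27.

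Among named genes, CYB2 turned to -0.0449 past the fusion, GAL10 and TOM70 to 0.0396 and 0.0764 without TMM factors, and SCEI to -0.00879 without the cycloheximide libraries. With 1 library left out COX1 ranged from -0.88 to 0.27, COX2 from -1.38 to 0.46, GAL10 from -0.244 to 0.0935, SCEI from -0.00885 to 0.555 and TOM70 from -0.178 to 0.0715. The replicate block made ERG6, HSP104, HXK1, JEN1, SSA2 and STI1 pass and MVD1, PEX11 and TIM22 not pass, no covariate ended 23 calls, DESeq2 added 19, and whole CDSs ended 3 and added 2. The direction of galactose (median 0.0462), HAP regulators (0.19) and genes with upstream reading frames (-0.0407) differed in fry, and that of gluconeogenesis and lactate use (0.13) without CYB2. With 1 library left out the medians ranged from -0.0924 to 0.109 for galactose, -0.23 to 0.46 for gluconeogenesis and lactate use, -0.23 to 0.12 for glycolysis and 0.0557 to 0.314 for HAP regulators.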

Other observations

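The lists in this part were chosen only after gene values were seen, as were the comparisons of splits of the libraries.

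Some genes of sulfur metabolism fell. Of 30 genes of methionine, S-adenosylmethionine and sulfate use, 8 fell, while the median of the list was 0.02: MET6, MET13, SAM2, SAM1 at -1.50 ± 0.26, the transporters SAM3 at -1.42 ± 0.12 and MUP1 at -0.96 ± 0.13, and SAH1 and ADO1, which clear S-adenosylhomocysteine, at -1.35 ± 0.19 and -1.35 ± 0.17. Of 19 genes of phospholipid synthesis and inositol or choline uptake, 3 fell: INO1, the phosphatidylserine decarboxylase PSD1 at -1.44 ± 0.26 and the choline transporter HNM1 at -1.36 ± 0.24. Of 6 cell wall mannoproteins known from cold or low oxygen, TIR1, TIP1 and TIR3 rose by 3.06 ± 0.43, 1.97 ± 0.40 and 1.62 ± 0.14. With 1 library left out at a time, SAM3, SAH1 and ADO1 passed in 5 of 6 fits. In the same fits MET6, MET13 and SAM2 passed in 4 each, MUP1 in 3 and SAM1 in 2. INO1 passed in 1, PSD1 and HNM1 in 2 each, TIR1 in 3, TIP1 in 1 and TIR3 in 5. These lists were drawn up because such genes had been seen to change, so a test of the lists would carry no evidence of its own and none is given.

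The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05, so these counts neither exclude nor show a grouping by chance. The real split gave 720 genes and the highest other 1, and 1 of the 10 splits, the real one, gave as many. For gene lists the real split gave 23 and the highest other 22, for control 1, clogger 1 and clogger 2 against the rest, and 1 of the 10 gave as many. For upstream ratios the real split gave 9 and the highest other 0, for early to late ratios 10 and 0, with 1 split as large for each. For codons the real split gave 0 and the highest other 1, so all 10 gave as many. Among the 4 splits that part all same-numbered pairs, the other 3 gave at most 19 lists and 0 genes.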
